A study of Mus musculus with 6 samples.

How the data were processed

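Small RNA was sequenced from RAW 264.7 cells, per the labels, in 3 untreated and 3 ox-LDL-treated samples. Per the labels' protocols, total RNA was extracted with Trizol, a small RNA fraction was purified on a gel, adaptors were ligated at both ends, and the cDNA was amplified and sequenced on an Illumina instrument. The authors deposited 1 table of estimated counts of reads per mature mouse miRNA, not scaled to a common total. Of its 6654 values, 117 in 40 entries were not whole (tolerance 1e-06). How the reads of miRNAs with several copies were divided is not given in the sources used here, nor are the aligner, the counter and the miRNA database version. The build is GRCm38.p5 per the submitters' processing notes. Adaptor ligation favours some RNA ends over others, so levels of different miRNAs are not compared as molecules, and PCR reads without molecular identifiers are not independent molecules.

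Samples were grouped by their titles, and columns were matched to samples by group and number in the column name. The estimated counts were rounded to whole numbers. Totals ran from 5502826 to 7373188 reads, so that 1 CPM stood for between 5.50 and 7.37 reads. Every pair of libraries differed beyond sampling noise (chi-square per degree of freedom 111 or more), so none was counted as 1 library given again, which does not show that the cultures were separate. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) with TMM factors and edgeR's own filter by group, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are after TMM scaling. Lists were tested with limma's camera (limma 3.58.1) at a preset correlation of 0.01 on log2 CPM with a prior count of 2, for lists with at least 3 tested members. Arm ratios were tested with limma on log2 of 5p over 3p reads with a pseudocount of 0.5. Composition was tested with exact permutation tests.

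The miRNAs named were set by a rule written before the data were examined. It takes the 10 largest rises and 10 largest falls among called entries with groups that do not overlap and a mean of at least 10 CPM, the 5 most abundant, 10 fixed miRNAs, 2 to 4 members of each list with the smallest p (3 were taken, a number set after the data were seen), and the 5 arm ratios with the smallest p. Other miRNAs named were chosen after their values were seen: miR-16-5p, miR-195a-5p, miR-17-5p, miR-17-3p, miR-20a-5p, miR-25-3p, miR-93-5p, miR-122-5p, miR-126a-3p, miR-199a-3p, miR-205-5p and miR-466i-5p in the lists, and those of the genomic clusters. The lists are the miR-29, miR-15/16, let-7, miR-30 and miR-181 families, the miR-17-92, miR-23/27/24, Dlk1-Dio3 and Sfmbt2 clusters, sets linked with Toll-like receptor signalling, cholesterol handling, p53, myeloid cells and alternative activation, and markers of erythroid cells, hepatocytes, muscle, endothelium, epithelium, neural cells and fibroblasts. The family lists hold main arms only, and the cluster lists hold both arms.

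Hairpin positions were taken from GENCODE annotation of GRCm38, which located 1099 of the 1109 entries. Hairpins that share a run of 20 bases with an annotated ribosomal, transfer, small nucleolar, small nuclear or other small RNA were marked, 35 entries in all. The annotation used holds few ribosomal and transfer RNA sequences, so this number is a lower bound. Values of 6 entries with at least 30 reads were identical to those of another entry in all 6 libraries, and their source is uncertain.

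On simulated data with the real means and library sizes, the edgeR step run on 467 entries recovered 15 of 65 miRNAs changed 1.5 times, 51 of 64 changed 2 times and 59 of 59 changed 4 times, and called 3 of 279 unchanged ones. Camera called 5 of 5 moved lists and 0 of 20 others. Members were drawn independently there, whereas the estimated correlation in the miR-15/16 family was 0.673. Because of such correlation, the count of 0 of 20 need not hold for the real lists. With the real libraries camera called 6 lists in a split that mixed the groups. That split keeps part of the group difference, so these 6 cannot be read as false calls. The arm test on 124 hairpins called 11 of 20 changed 2 times, 20 of 20 changed 4 times and 1 of 84 unchanged. Alternatives tried were RLE factors, library totals alone, no filter, a mean of at least 10 CPM, a replicate block, leaving out each library, DESeq2 (1.42.0), limma-voom, other thresholds, other list tests and other arm minimums and pseudocounts. Median centring, counting identical entries once, leaving out entries that match other small RNA, and grouping by genomic position were added after the data were seen.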

Results

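Mature microRNAs (miRNAs) were counted by small RNA sequencing in RAW 264.7 cells, a mouse macrophage-like line. There were 3 libraries of untreated cells (control) and 3 of cells given oxidized low-density lipoprotein (ox-LDL) for 48 h (the oxLDL group). Ox-LDL is a modified lipoprotein that macrophages take up as they turn into lipid-laden foam cells. The control libraries held 7373188, 7123499 and 6570099 miRNA reads, and the oxLDL libraries 5502826, 6572486 and 6310747. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these samples, which may be technical. The labels give no time for the control cells and their columns are named for 0 h, so time in culture was not separated from the treatment. They also give no day or batch of preparation, so an effect of either could not be checked.

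The comparison of oxLDL with control asked which miRNAs differ in ox-LDL-treated macrophages. After ox-LDL, miR-146a-5p, an inflammation-inducible miRNA, rose 2.82 times, from 4591 ± 321 to 12962 ± 2176 CPM (reads scaled to a common library size, mean ± SD, n = 3). The hypoxia-linked miR-210-3p rose 3.20 times, from 456.4 ± 30.3 to 1460.1 ± 221 CPM. Both arms of the miR-708 hairpin rose, miR-708-3p 6.10 times and miR-708-5p 5.90 times. In the other direction miR-92a-3p, a member of the miR-17-92 family of clusters, was 2.97 times lower, at 10773 ± 282 against 32017 ± 3319 CPM. The inflammatory miR-155-5p was 1.55 times lower, at 190.7 ± 15.96 against 296.5 ± 59.8 CPM.

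Of 1109 entries, 475 had enough reads to be tested, and 217 passed an adjusted p of 0.05 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of these, 103 were higher and 114 lower in oxLDL, and 119 changed at least 2 times (51 higher, 68 lower). The groups did not overlap for 282 of the 475 entries (59.4%, against 10% by chance). The share of called entries that were higher was 47.5%, and it was 34.2% with library totals alone (82 of 240) and 58.7% after centring on the median miRNA (131 of 223), a setting added after the data were seen. The median log2 fold change of all tested entries was -0.13 with the scaling used and -0.28 with library totals, so small changes are relative to that median.

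**Figure D1:**
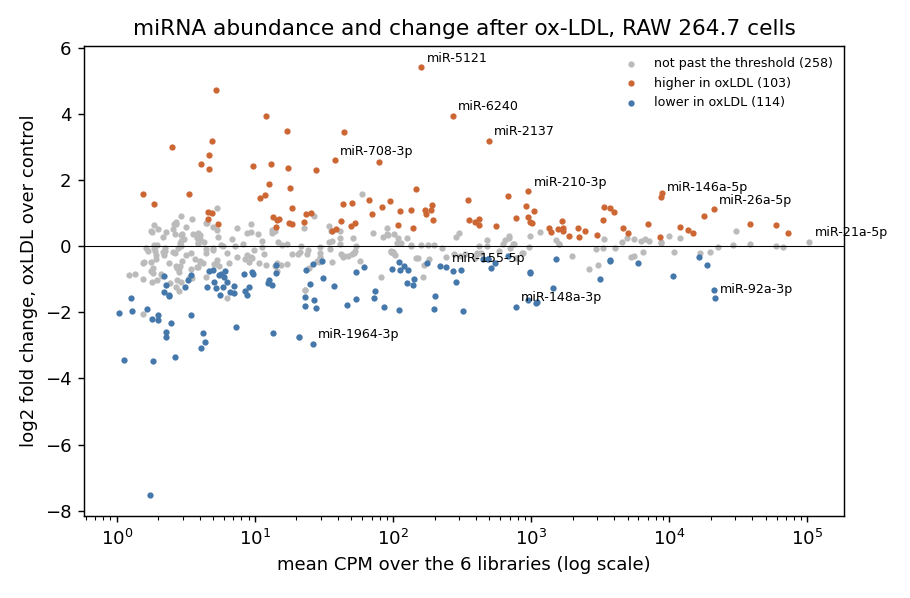
Log2 fold change of oxLDL over control (vertical) against the mean CPM over the 6 libraries (horizontal, log scale), 1 point per tested entry; orange points were higher and blue points lower in oxLDL past the threshold. Called entries include miR-5121 (log2 fold change 5.42) and miR-1964-3p (-2.94).

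The largest rises among entries with at least 10 CPM and groups that did not overlap were those of miR-5121 (42.8 times), miR-6240 (15.5 times), miR-3473e (15.5 times), miR-714 (11.3 times), miR-5126 (11.1 times) and miR-2137 (9.21 times). The 2 miR-708 arms, miR-1291 (5.60 times) and miR-3473b (5.17 times) followed. The log2 fold change of miR-3473e was 4.77 without control replicate 1, against 3.95, and that of miR-5126 was 4.11 without control replicate 3, against 3.47. Their control reads were 20, 4 and 8, and 42, 26 and 93. Several of these sit in or match other RNA. The miR-5121 hairpin (GRCm38, chromosome 7, 45126918 to 45126991, minus strand) lies in an exon of the ribosomal protein gene Rpl13a and shares a run of 20 bases with a small nucleolar RNA (snoRNA). The hairpin of miR-1291 (chromosome 15, 98519762 to 98519878, minus strand, intron of Kansl2) also matches a snoRNA, and that of miR-3473b (chromosome 10, 41670739 to 41670793, plus strand, antisense to an intron of Ccdc162) matches an annotated small RNA of another class. No hairpin of miR-714 was located in the annotation. The miR-708 hairpin (chromosome 7, 96249424 to 96249532, plus strand) lies in an intron of Tenm4 and had no such match. Those of miR-6240, miR-3473e, miR-5126 and miR-2137 had none either. The annotation used holds few ribosomal and transfer RNA sequences, so a match to those classes was hardly checked for any of these entries. In edgeR's test the adjusted p was 5.32e-05 for miR-5121 (log2 fold change 5.42, SE 0.362) and for miR-708-3p (2.61, SE 0.153).

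The largest falls, under the same limits of 10 CPM and no overlap, were those of miR-1964-3p (7.69 times lower), miR-128-1-5p (6.68 times), miR-449c-5p (6.21 times), miR-6539 (3.89 times), miR-18a-3p (3.79 times), miR-222-5p (3.69 times), miR-374c-3p (3.68 times), miR-25-5p (3.59 times), miR-148a-3p (3.56 times) and miR-301a-5p (3.47 times). The hairpin of miR-1964-3p (chromosome 7, 29773294 to 29773376, plus strand) lies in an intron of Zfp84. None of these 10 had a hairpin that matched other small RNA. By level, miR-148a-3p went from 1206 ± 338 to 339.4 ± 159 CPM and miR-6539 from 512.6 ± 32.2 to 131.8 ± 17.9 CPM.

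The 5 most abundant miRNAs changed little or rose slightly. The abundant miR-21a-5p was at 98668 ± 8736 CPM in control and 109115 ± 6806 CPM in oxLDL (log2 fold change 0.15, edgeR adjusted p = 0.255). The myeloid miR-142a-5p (log2 fold change -0.01) and let-7f-5p (0.02) did not pass either. The sign of these small values depended on the scaling, since miR-21a-5p and let-7f-5p turned negative with library totals and miR-142a-5p turned positive with RLE factors. Among the abundant miRNAs, miR-22-3p rose 1.58 times (edgeR adjusted p = 0.000454) and miR-27b-3p 1.31 times (edgeR adjusted p = 0.0130), the latter not past the threshold with library totals or without control replicate 2 or oxLDL replicate 2 or 3 (adjusted p up to 0.0787). Of the other miRNAs fixed beforehand, miR-33-5p, which lies in an intron of the sterol regulator gene Srebf2 (chromosome 15, 82198122 to 82198190, plus strand), was at 134.7 ± 20.3 and 134.7 ± 19.3 CPM. The myeloid miR-223-3p (log2 fold change 0.57), miR-125b-5p (-0.17), miR-142a-3p (0.23), miR-27a-3p (0.25) and miR-9-5p (-0.31) did not pass. Some of these passed in other settings: miR-223-3p without oxLDL replicate 1 (log2 fold change 0.82, adjusted p = 0.0130) and with no filter on low counts (adjusted p = 0.0293), miR-125b-5p with library totals (adjusted p = 0.0163) and with a mean of at least 10 CPM (adjusted p = 0.0392), miR-27a-3p without control replicate 3 (adjusted p = 0.0415) and with median centring (adjusted p = 0.0411), and miR-142a-3p with median centring (adjusted p = 0.0330). The log2 fold change of miR-9-5p was 0.01 without control replicate 2.

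**Figure D2:**
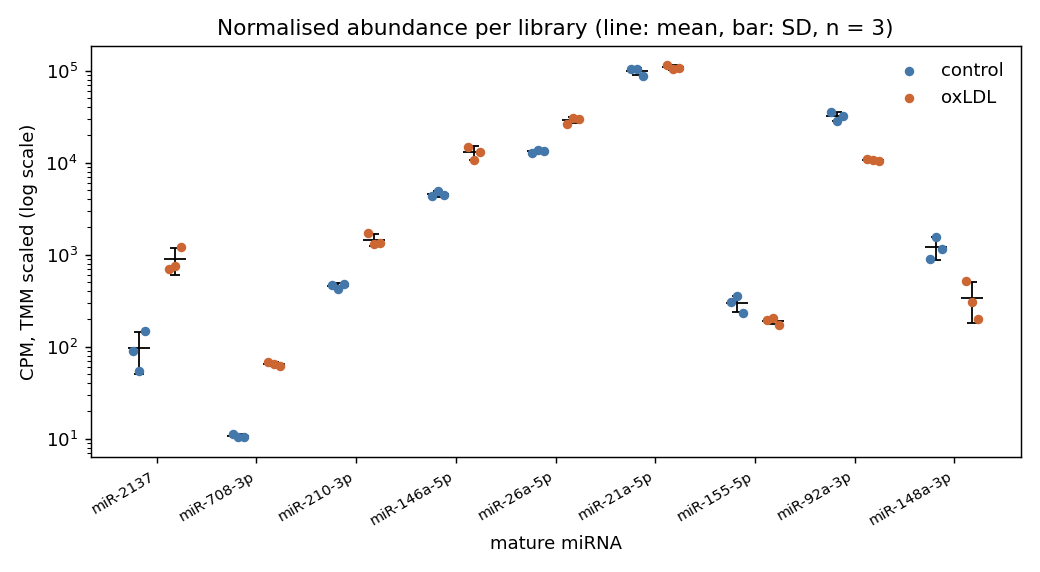
CPM after TMM scaling (vertical, log scale) of 9 miRNAs in each library; points are libraries, lines the mean and bars the SD of 3. The groups of miR-146a-5p lie apart (4591 and 12962 CPM on average), and those of miR-21a-5p overlap.

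The fall of miR-155-5p was close to the threshold (log2 fold change -0.64, SE 0.176, edgeR adjusted p = 0.0197). It did not pass without control replicate 1 (adjusted p = 0.0628) or without oxLDL replicate 3 (adjusted p = 0.0607). The other arm of its hairpin, miR-155-3p, fell 2.40 times at low counts, from 7.34 ± 1.06 to 3.04 ± 0.220 CPM.

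Lists of related miRNAs, fixed before the data were examined, were compared next. Over all tested entries 217 of 475 passed, 103 higher and 114 lower, so list counts near that share do not set a list apart. In the miR-29 family, listed by its main arms only, all 3 tested members were higher, also when adjusted over the list alone. Its members miR-29c-3p, miR-29b-3p and miR-29a-3p rose 2.11, 1.85 and 1.42 times. The other arms of these hairpins went both ways. Among them miR-29b-1-5p fell (log2 fold change -1.08) and miR-29c-5p rose (0.58), while miR-29b-2-5p (0.42) and miR-29a-5p (0.04) did not pass. In the miR-15/16 family 4 of 5 members rose, among them miR-195a-5p (2.29 times), miR-497a-5p (1.72 times), miR-15a-5p (1.47 times) and miR-15b-5p (1.46 times), and 4 when adjusted over the list alone. The call of miR-195a-5p was lost without control replicate 1 (edgeR adjusted p = 0.0661). Its most abundant member miR-16-5p was at 25676 and 35749 CPM and did not pass, though it did without oxLDL replicate 1 (log2 fold change 0.76, adjusted p = 0.00806) and with no filter (adjusted p = 0.00101). Among other arms of these hairpins, miR-16-1-3p (log2 fold change -0.78) and miR-16-2-3p (-0.47) fell. The arms miR-15a-3p, miR-15b-3p and miR-195a-3p did not pass. Whether the family or the kind of arm set these list results was not tested. Of the miR-17-92 and paralogous clusters, 10 of 19 members were lower and 3 higher (10 and 3 adjusted over the list alone), with a median log2 fold change of -0.45.

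None of the 18 lists with 3 or more tested members passed limma's camera test after Benjamini-Hochberg adjustment. The count at an unadjusted p under 0.05 was 3 with camera, and fry, a rotation test of whether a list moves on balance 1 way, called 2. Camera compares a list with all other tested entries and fry does not, so their p-values answer different questions. With 217 of 475 entries called, fry can call a list that moved no more than the rest. The camera adjusted p was 0.135 for the miR-29 family, the miR-15/16 family and the miR-17-92 clusters, and adjusted p = 0.885 with an estimated correlation for each. That correlation was 0.198, 0.673 and -0.018 in turn. For the miR-17-92 clusters it lay under the preset 0.01, yet camera's unadjusted p went from 0.0226 to 0.0684. The higher p of that list thus does not come from correlation between its members. With fry the adjusted p was 0.000661 for the miR-17-92 clusters (lower) and 0.00223 for the miR-29 family (higher). With no filter on low counts camera called these same 2 lists (adjusted p = 0.0370 for each), and with a mean of at least 10 CPM the miR-17-92 clusters alone (adjusted p = 0.0268).

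In the miR-17-92 clusters the falls included miR-92a-1-5p (3.08 times lower), miR-18a-3p and miR-25-5p beside miR-92a-3p. They also included miR-25-3p (1.43 times lower) and miR-17-5p (1.34 times lower, edgeR adjusted p = 0.0513 with median centring). The rises were those of miR-17-3p (1.67 times), miR-93-5p (1.27 times) and 1 member of the Mir20b/Mir18b/Mir106a cluster. The last was the largest rise of the list (log2 fold change 1.27). The call of miR-93-5p was lost with library totals, the replicate block and no filter, and without control replicate 1 or 3 or oxLDL replicate 2 (adjusted p up to 0.137). The fold change of miR-20a-5p (log2 -0.08; 0.05 with median centring) did not pass. The abundant miR-92a-3p has 2 hairpins, in an exon of Mir17hg (chromosome 14, 115044427 to 115044506, plus strand) and on the X chromosome (52741838 to 52741928, minus strand), and its reads could come from either.

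Of 20 tested miRNAs known to be induced by Toll-like receptor or NF-kB signalling, 5 rose and 4 fell (5 and 4 adjusted over the list alone). The list included miR-146a-5p, which rose, miR-125a-5p, which fell 1.86 times from 13801 ± 1298 to 7439 ± 676 CPM, and miR-155-3p. Of 17 miRNAs linked with cholesterol handling, 3 rose and 4 fell (3 and 4 over the list alone). The rises included miR-26a-5p (2.18 times, from 13274 ± 583 to 28936 ± 2173 CPM) and miR-101a-3p (1.72 times), and miR-148a-3p, described as a repressor of the LDL receptor, was among the falls. Of 9 myeloid-enriched miRNAs 1 rose and 1 fell (1 and 1 over the list alone). Of 9 miRNAs linked with alternative activation 1 rose and 3 fell (1 and 3 over the list alone), among the latter miR-378a-5p (1.59 times lower; edgeR adjusted p = 0.0706 without oxLDL replicate 2).

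The seed families were mixed. In the let-7 family 2 of 9 rose (1 adjusted over the list alone), miR-98-5p 2.24 times and let-7e-5p 1.24 times, and let-7g-5p (log2 fold change 0.31) did not pass, though it did with RLE factors (adjusted p = 0.0376), without oxLDL replicate 3 (adjusted p = 0.0481) and with median centring (adjusted p = 0.0203). In the miR-30 family 1 of 5 rose (miR-30b-5p, 1.37 times) and 2 fell (miR-30c-5p 1.36 times, miR-30d-5p 1.48 times), the same counts as over the list alone. In the miR-181 family miR-181a-5p rose 1.33 times and miR-181b-5p fell 1.97 times among 4, and the list alone gave 1 and 2. The fall of miR-181d-5p (1.68 times lower, edgeR adjusted p = 0.0713) passed in 5 other settings, among them without control replicate 3 (0.00919) or oxLDL replicate 1 (0.0457). Of the 11 members of the miR-23/27/24 clusters 3 rose, with miR-23b-3p at 1.47 times, and 2 fell, miR-27a-5p (2.83 times lower) and miR-23a-5p (2.33 times lower), as over the list alone. Of 7 miRNAs described as p53 targets 2 rose (none over the list alone), miR-192-5p (1.68 times) and miR-107-3p (1.34 times). In the Dlk1-Dio3 cluster 2 of 4 fell (2 over the list alone), miR-127-3p 2.31 times and miR-411-5p 1.91 times, at means under 10 CPM. The Sfmbt2 cluster, with near-identical copies, had 1 tested member, miR-466i-5p, which did not pass. Among these, calls of let-7e-5p, miR-181a-5p, miR-30b-5p, miR-23b-3p, miR-192-5p and miR-107-3p were lost with library totals. The replicate block ended those of let-7e-5p, miR-181a-5p, miR-107-3p and miR-411-5p (edgeR adjusted p from 0.0621 to 0.135). Calls were also lost when 1 library was left out: let-7e-5p with any but oxLDL replicate 1 left out (edgeR adjusted p up to 0.214 over all settings), miR-192-5p with any but control replicate 2 (up to 0.0921), miR-181a-5p without control replicate 1 or 3 or oxLDL replicate 2 or 3 (up to 0.115), miR-107-3p and miR-411-5p without control or oxLDL replicate 2 or 3 (up to 0.143 and 0.0834), miR-127-3p without control replicate 2 or 3 or oxLDL replicate 1 or 2 (up to 0.0863), and miR-23b-3p without control replicate 1 (0.0509).

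Markers of other cell types were compared as lists too. The erythroid and serum list had a median log2 fold change of -1.33 over 5 members, 1 of which passed (4 over the list alone), miR-451a at 80.3 ± 54.0 against 26.8 ± 13.1 CPM. Of these members miR-486a-5p and miR-486b-5p have identical reads, so that 1 measurement is counted for both, and the median is its value. The call of miR-451a did not hold without control replicate 2 (edgeR adjusted p = 0.0773), oxLDL replicate 2 (0.110) or oxLDL replicate 3 (0.0766). Control replicate 2 held more of these reads than the other controls, with 1075 reads of miR-451a against 316 and 406, and 486.5 of miR-486a-5p against 134 and 122.5. Without it the log2 fold change was -0.92 for miR-451a and -0.44 for miR-486a-5p, against -1.33 with it for the latter. The latter passed with library totals (edgeR adjusted p = 0.0438), with no filter, with DESeq2 (0.0157) and without control replicate 3 (0.0295). The hepatocyte marker miR-122-5p, also highest in that library, had 136, 647 and 37 reads in the controls and 13, 12 and 71 in oxLDL, and did not pass (edgeR adjusted p = 0.0655; it passed over the list alone, with library totals, with no filter, and without control replicate 3 at 0.0223 or oxLDL replicate 3 at 0.0273). Without control replicate 2 its log2 fold change was -1.10 in place of -2.73, and without oxLDL replicate 3 it was -4.03. None of 4 muscle markers passed, with miR-133a-3p at 201.6 ± 215 and 136.4 ± 84.3 CPM. Control replicate 2 had 3394 reads of it against 622 and 516 in the other controls, and without that library its log2 fold change was 0.77 in place of -0.56. With no filter it passed (edgeR adjusted p = 0.0268), as did miR-1a-3p (log2 fold change -1.54, adjusted p = 7.71e-06) and miR-133b-3p (adjusted p = 0.0362). These passes came despite a wide spread between the controls, as did that of miR-122-5p with no filter (edgeR adjusted p = 8.81e-22). Without control replicate 2, which had 163 reads of miR-1a-3p against 20 and 29 in the other controls, the log2 fold change was -0.10 for miR-1a-3p (-1.56 with it) and 0.22 for miR-133b-3p (-0.96 with it). The endothelial miR-126a-3p fell 2.13 times, the 1 tested member, a call lost without control replicate 2 or 3 or oxLDL replicate 2 (edgeR adjusted p up to 0.0919). Of 9 fibroblast and smooth muscle markers 4 fell and 1 rose (4 and 1 over the list alone). The falls included miR-214-3p (5.41 times lower) and miR-214-5p (3.89 times lower), both at means under 10 CPM. Reads of miR-214-5p were 14, 22 and 10 in control and 4, 2 and 3 in oxLDL. The rise was that of miR-10a-5p (1.61 times). Counts of miR-199a-3p equal those of an identical copy, and it did not pass (log2 fold change 0.07, and -0.09 with library totals). Of 10 epithelial markers 4 rose and 2 fell (5 and 2 over the list alone), and the rises miR-183-5p (2.29 times) and miR-182-5p (1.90 times, to 23614 ± 912 CPM) were abundant in these cells. The falls were those of miR-203-3p (2.66 times lower) and miR-205-5p (6.20 times lower), both at means under 10 CPM over the 6 libraries. Of 4 neural markers 1 rose, miR-219a-5p (1.59 times, none over the list alone), a call that any left-out library ended (edgeR adjusted p up to 0.173).

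Median, mean and camera direction differed in sign for some lists. The Toll-like receptor list had a median of -0.12 and the cholesterol list a mean of -0.17, both ranked upward by camera. The miR-23/27/24 clusters had a median of 0.16 and a mean of -0.13, the epithelial list 0.43 and -0.02, and the neural list -0.12 and 0.03.

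The ratio of the 5p to the 3p arm of a hairpin does not depend on library scaling, and it was compared for 124 hairpins. For miR-210 the log2 ratio of 5p to 3p reads fell from -4.65 ± 0.238 to -7.47 ± 0.0754 (mean ± SD, n = 3), a change of -2.82, as miR-210-3p rose while miR-210-5p fell (log2 fold change -1.17). For miR-671 it rose from -0.32 ± 0.405 to 2.13 ± 0.284. The ratio fell for miR-301a (change -2.01) and miR-27a (-1.76) and rose for miR-18a (1.70), in each case with the less abundant arm falling. With limma 49 of the 124 ratios passed after Benjamini-Hochberg adjustment, with an adjusted p of 0.000104 for miR-210, 0.00131 for miR-671, 0.00202 for miR-301a and miR-18a, and 0.00282 for miR-27a. At least 10 reads on average were asked of both arms.

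**Figure D3:**
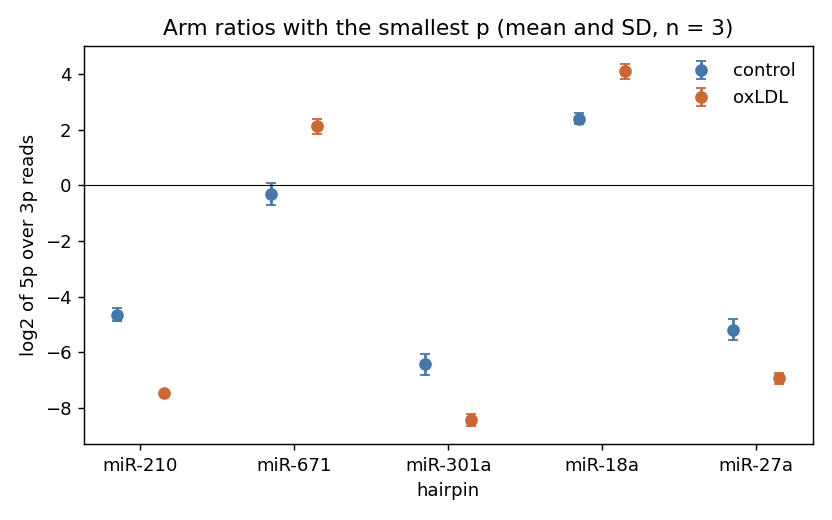
Log2 of 5p over 3p reads (vertical) for the 5 hairpins with the smallest p; points are means of 3 libraries and bars the SD. The mean miR-671 ratio went from -0.32 in control to 2.13 in oxLDL.

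The share of reads held by the most abundant miRNAs differed by little. The 10 most abundant miRNAs took 50.4% ± 0.890 of the reads in control and 53.7% ± 1.44 in oxLDL (SD, n = 3; exact permutation test, 2-sided, p = 0.1, the smallest that 3 against 3 samples allow). With the 20 most abundant the shares were 70.5% ± 1.12 and 70.0% ± 1.52, a difference of -0.553 percentage points within the spread (exact permutation p = 0.6). There were 859 ± 5.57 entries with reads in control and 819 ± 10.4 in oxLDL (exact permutation p = 0.1). Entries with at least 10 reads numbered 493 ± 3 in control and 437.3 ± 10.5 in oxLDL (exact permutation p = 0.1). The totals were 7022262 ± 411004 and 6128686 ± 557587 reads, a difference of -893576 (exact permutation p = 0.2).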

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

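Centring on the median miRNA, counting identical entries once, leaving out entries that match other small RNA, and the tests of genomic clusters were chosen only after the data were seen. The planned pseudocount alternative applied to normalized values and was not run on counts. Across scalings, filters, tools and left-out libraries the count of called miRNAs ran from 161 to 252, against 217, and none of the 217 changed sign where it was tested. With library totals 196 of the 240 calls were among the 217. It was 119 (51 higher, 68 lower) with a change of at least 2 times and 137 (64 lower) at an adjusted p under 0.01, because those thresholds are stricter. Leaving out 1 library gave 161 to 211 calls. Entries of few reads limit what the test can call. With no filter, entries of wide spread could pass, so calls gained only in that setting are weak support. There miR-1a-3p, with 20, 163 and 29 control reads and 25, 12 and 18 in oxLDL, had an edgeR adjusted p of 7.71e-06, against 0.137 in the comparison reported.

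The labels do not say whether samples of the same number were paired. Deviations of same-numbered samples correlated at -0.30, -0.23 and -0.12, which gave no sign of pairing. So few samples cannot settle it. With the replicate block 178 miRNAs (87 higher, 91 lower), 39 arm ratios, 0 lists and 1 genomic cluster were called. No sample correlated best with its own number.

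The list count of 0 became 2 with no filter on low counts and 1 with a mean of at least 10 CPM, and the cause was not tested. It became 2 with fry, which, unlike camera, does not compare a list with the other entries. The arm ratio count ran from 34 to 51, against 49. The difference in the share of reads was -0.553 points for the top 20 in place of the top 10, within the spread (exact permutation p = 0.6). That in entries detected was -55.7 with at least 10 reads in place of -40. The cause of either was not tested. The count of genomic clusters, 1, became 0 with an estimated correlation, 2 with library totals, and 0 to 2 without 1 library; the cause was not tested.

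The lists that passed in other settings had median log2 fold changes of -0.436 (miR-17-92 clusters) and 0.891 (miR-29 family) with no filter, -0.613 (miR-17-92 clusters) with a mean of at least 10 CPM, and -0.447 and 0.880 with fry.

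The named miRNAs that changed direction were not past the threshold in the comparison reported, and the values are log2 fold changes. With RLE factors miR-142a-5p came to 0.0359 and miR-33-5p to 0.0453. With library totals miR-21a-5p came to -0.0036 and let-7f-5p to -0.130, and with a mean of at least 10 CPM let-7f-5p came to -0.0896. The value of miR-33-5p was 0.0086 with no filter, 0.0021 with the replicate block, 0.00099 with limma-voom and 0.0054 without entries matching other small RNA. With DESeq2 miR-142a-5p came to 0.0359 and miR-33-5p to 0.0451, and with median centring to 0.119 and 0.129. With 1 library left out the ranges were -0.117 to 0.0390 for miR-142a-5p, -0.141 to 0.178 for let-7f-5p, -0.148 to 0.0868 for miR-33-5p, -0.811 to 0.0058 for miR-9-5p, -1.24 to 0.155 for miR-136-3p, -1.68 to 0.222 for miR-133b-3p, -1.20 to 0.768 for miR-133a-3p and -0.377 to 0.0998 for miR-138-5p. Of the miRNAs named after their values were seen, miR-199a-3p came to -0.0888 with library totals, -0.0449 with a mean of at least 10 CPM and from -0.0570 to 0.121 with 1 library left out, miR-466i-5p ranged from -0.0068 to 0.622 with 1 library left out, and miR-20a-5p came to 0.0478 with median centring. The cause was not tested.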

Other observations

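The tests of minor arms and of names without an arm, and those of genomic clusters, were chosen only after the result was seen.

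Groups of miRNAs that lie side by side in the genome were compared. The X-linked cluster Mir500/Mir501/Mir362/Mir188/Mir532 (GRCm38, 7237683 to 7248497, minus strand) had 5 of 9 tested members higher and none lower, with miR-501-3p at 2.67 times, miR-362-5p at 2.64 times and miR-362-3p at 2.60 times. It was the 1 cluster of 28 called by limma's camera (adjusted p = 0.0416; adjusted p = 0.840 with an estimated correlation). The call was lost without control replicate 1 or control replicate 2. The Mir182/Mir96/Mir183 cluster (chromosome 6, 30165918 to 30169737, minus strand) had 3 of 5 members higher with camera's adjusted p = 0.0764. For Mir221/Mir222 (X chromosome, 19146294 to 19146971, minus strand) 3 of 4 members were lower, with miR-222-3p falling from 30067 ± 4445 to 11936 ± 2190 CPM, and the cluster did not pass (adjusted p = 0.430).

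The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 217 miRNAs and 49 arm ratios, and the highest of the others called 0 of each, so that 1 of 10 splits reached the real count for miRNAs and for arm ratios. For the lists the real split called 0 and another called 6 (10 of 10 splits as large), and a real count of 0 makes this hold whatever the samples, so it says nothing. For genomic clusters the real split called 1 and another 2 (3 of 10 as large). For the median change of minor arms the real split gave 0.412 in size and the highest other 0.153 (1 of 10 as large). Every other split has libraries of both groups on both sides, which shrinks a group difference and adds it to the spread. Lower values in those splits for miRNAs, arm ratios and minor arms were thus largely given in advance by any group difference, whatever its cause.

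For the 18 called entries at least 4 times higher in oxLDL, the median log2 fold change was between 2.74 and 3.02 under 4 scalings. These entries were chosen by their rise under the main scaling, so a high median was largely given in advance. The values show only that the scalings differed by less than these rises. Of the 16 with a located hairpin, 5 matched other small RNA (31.2%), against 21 of 453 others (4.64%; Fisher's exact p = 0.00102, 2-sided). Names without an arm, taken as a sign of weakly supported annotation, made up 11 of 18 against 42 of 457 (Fisher's exact p = 2.13e-07). A candidate explanation for part of these rises is thus that fragments of other RNA were counted as miRNA, and a change in such fragments with ox-LDL stays open. The miR-708 arms, at 6.10 and 5.90 times, had neither mark.

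The lower median of the miR-17-92 and paralogous clusters was not explained by scaling, being at most -0.32 under 4 scalings, nor by 1 library, being at most -0.44 with any of the 6 left out. Several falling members were minor arms, and the part that the general fall of minor arms, described next, has in this median was not tested. A treatment effect, time in culture and a day or batch that the labels do not give stay open, untested.

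For the less abundant arm of a hairpin relative to the other arm, the median log2 change over 124 hairpins was -0.41, with 86 lower and 38 higher, and in 38 of the 49 called ratios it was the arm that fell relative to the other. The medians of this log2 ratio per library overlapped between the groups: -3.83, -4.15 and -3.89 in control replicates 1 to 3, and -4.12, -4.20 and -4.24 in oxLDL. A bias of the 5p or 3p end is argued against, as hairpins with a minor 5p arm (median -0.46) and a minor 3p arm (-0.39) moved alike, the highest of their medians in 9 pairs of libraries being -0.13. Low counts in shallower libraries are argued against as the sole account. With reads thinned to 5502826 per library and at least 100 reads in the minor arm, the median over 70 hairpins was -0.28, and between -0.37 and -0.17 over the 9 pairs. That is smaller in size than the -0.41 over all 124 hairpins, so low counts may carry part of the fall. A treatment effect, time in culture and a day or batch that the labels do not give stay open, untested.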
